A study of Mus musculus with 2 samples.

How the data were processed

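ChIP-seq of H3K4me3 was done on kidneys of mice on postnatal day 0, in 2 libraries that the labels call biological replicates, both assigned to 1 group by their labels. The antibody and tissue come from the labels. The files used here are 4 deposited peak lists on mm10: 1 per replicate, 1 called over both replicates together, and 1 of replicated peaks. Per the deposited descriptions of the files, the replicated list was derived from the pooled list and the replicate lists. All of its 22403 peaks were found with identical coordinates and values in the pooled list, so its peaks are peaks of the pooled call that met the authors' rule for replication. That rule, the aligner, the peak caller and their versions are not given in the sources used here, and neither is the number of reads. Each peak carries a fold enrichment, deposited as the signal value of the peak caller, and a −log10 q, both computed by the authors and used here only to describe, rank or filter peaks within a list. What the fold enrichment is relative to is not given in the sources used here. The deposited descriptions name the same further input files for each list, with no role given, so the lists share that input. The lists reach weak peaks: 1955 peaks of replicate 1, 1413 of replicate 2 and 22 of the replicated list have a q above 0.05.

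Peak callers set narrow peaks wherever signal dips, so a broad stretch of the mark is often cut into several peaks, and deeper libraries yield more and wider ones. With the depth unknown, widths and numbers were compared between gene groups within a replicate, and between replicates only as a description. Intervals on shares are 95% Wilson intervals and cover counting error only.

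Gene positions were those of GENCODE release M21 for mm10, with 21938 protein-coding genes and 93513 start sites of their annotated transcripts. The reference genome was checked against the lists: on all 21 chromosomes the last peak and the last gene ended within the reference length. A gene was called marked when a replicated peak lay within 1 kb of any of its start sites. A peak near start sites of more than 1 gene marked each of them, so a call does not assign the peak to a gene. Remaining peaks were placed by their midpoint in exons, introns or between genes. Peaks of different replicates were called overlapping from 1 shared bp. For widths, the peaks of each replicate's own list were merged when at most 1 kb apart, and a gene took the widest domain within 1 kb of its start sites. The log2 widths of the 2 replicates were averaged, and genes were tested only if marked and with a domain in both replicates (14460 genes, in 12922 separate domains). Broad means the widest 5% of these genes within a replicate.

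The 25 gene lists, the tests of marking and width, the alternatives and the rule for named genes were fixed before the data were examined. They cover 9 kidney cell type lists with 144 genes in all, lists of blood cells, other organs and generally used genes, and gene families matched by symbol. The kidney lists were written from general knowledge of marker genes and not chosen on these samples. List symbols were matched to the annotation. Kirrel1 was matched by an older symbol, Ahsp was not found, and 3 symbols (Aldoa, Olfr290 and Vmn1r216) are carried by 2 gene records each, so the 14 glycolysis records stand for 13 symbols. Marking was tested with Fisher's exact test per list against all other protein-coding genes, two-sided. Widths were tested with a permutation test of the mean log2 width with 100000 resamples, two-sided, for the 14 lists with at least 10 marked members that had a width. Benjamini-Hochberg adjustment ran over the lists of each family, with a threshold of 0.05. The exact test of broad domains per list, in the last comparison, was not among the tests fixed beforehand. With 2 samples of 1 group there is no test between groups and no test of a sample standing apart from its group. The tests run over genes, and genes that share a domain or a promoter are not independent.

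Genes were named by rule: the 10 widest domains, the 3 widest marked members and up to 4 unmarked members of each list in alphabetical order, the 5 genes whose width differed most between the replicates, the 3 strongest peaks of each replicate without overlap, and Wt1, Six2 and Ren1. Members of lists named as examples beyond that rule were chosen after their values were seen.

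The alternatives were a reciprocal overlap of 50%, a −log10 q of at least 2 or 5, promoter windows of 500 and 2500 bp, the pooled list, the 5' end of the gene as its only start site, either replicate's own list alone, merging distances of 0 bp and 3 kb, the widest 1% and 10% as broad, widths from the replicated list, and matching on promoter CpG content. CpG content was the highest observed over expected ratio within 500 bp of a gene's start sites, in 10 deciles, computed from the genome. Added after the data were seen were a background without olfactory and vomeronasal receptor genes, each domain counted once, and permutation within deciles of peak strength.

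The overlap, list and width steps were tested on simulated data before use. With 15 genes per list and 97% of them marked, Fisher's exact test passed 69% of changed and 4% of unchanged lists at an unadjusted threshold of 0.05 among 21938 genes. With domains widened by a log2 shift of 1, the permutation test of width passed 70% of changed and 5% of unchanged lists of 15 genes. Marking and widths were drawn independently for each of the 21938 genes, with widths from all merged domains of replicate 1. The real width tests use only marked genes, which can share domains, so their pass rates may differ. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used. Peaks on scaffolds with no position within an assembled chromosome and the mitochondrial genes were left out of the gene comparisons.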

Results

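H3K4me3, the trimethylation of lysine 4 of histone H3 that marks the promoters of active and poised genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole kidney of mice on the day of birth. At this age the outer kidney still holds nephron progenitor cells, and new nephrons keep forming. The series holds 1 group with 2 biological replicates, each made from pooled mice of both sexes. Replicate 1 was a pool of 15 mice, and the labels give no number of mice for replicate 2. There was no second tissue, age or treatment, so the comparisons the design allows are those between the replicates and those between groups of genes within this tissue. The depth of the libraries is unknown here, because the files hold peaks and not reads. The authors' list for replicate 1 held 30352 peaks covering 30803059 bp, and that for replicate 2 held 30327 peaks covering 33208887 bp. Their list of replicated peaks held 22403 peaks covering 33371501 bp, with a median width of 1318 bp and a median fold enrichment of 16.4. All coordinates are on mm10.

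The first comparison asked how far the replicates shared their peaks. The domain at Wt1, a transcription factor gene of nephron progenitors and podocytes, was 11487 bp wide in replicate 1 and 12623 bp in replicate 2. That at Six2, which keeps nephron progenitors undifferentiated, measured 6545 and 7574 bp. Ren1, the renin gene of the juxtaglomerular cells, had no peak in replicate 1 and a single peak of 200 bp in replicate 2 (chromosome 1, 133352217 to 133352416, fold enrichment 3.99). Over the whole lists, 81.0% of the replicate 1 peaks overlapped a replicate 2 peak by at least 1 bp (95% Wilson interval 80.5 to 81.4). The share was 76.3% of the replicate 2 peaks (75.8 to 76.8). The lists shared 27730144 bp, or 76.4% of the bases covered by either. Across overlapping peaks, which are not independent replicates, Spearman's rho of the authors' fold enrichment was 0.817.

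The peaks found in 1 replicate only were narrow and weak. They numbered 5773 in replicate 1, with a median width of 219 bp and a median fold enrichment of 2.98, against 1018 bp and 10.8 for the peaks of that replicate with an overlap. In replicate 2 they numbered 7190, with medians of 233 bp and 3.27, against 1201 bp and 15.0. None of those in replicate 1 and 5 of those in replicate 2 lay above the median strength of their own list. The strongest peaks without a partner in replicate 1 lay at the promoters of Scn3b, a sodium channel subunit gene (chromosome 9, 40269026 to 40269588, fold 6.40), of the histone gene Hist1h2bb (chromosome 13, 23746706 to 23746988, fold 6.20) and of the antisense transcript A530095I07Rik (chromosome 13, 69544131 to 69544460, fold 5.93). Those of replicate 2 lay in an intergenic stretch 11474 bp from the noncoding gene B130034C11Rik (chromosome 16, 87507547 to 87507923, fold 10.2), at the histone gene Hist1h3c (chromosome 13, 23745321 to 23745575, fold 9.19) and at the noncoding gene 5730437C11Rik (chromosome 3, 98941251 to 98941602, fold 8.30).

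**Figure D1:**
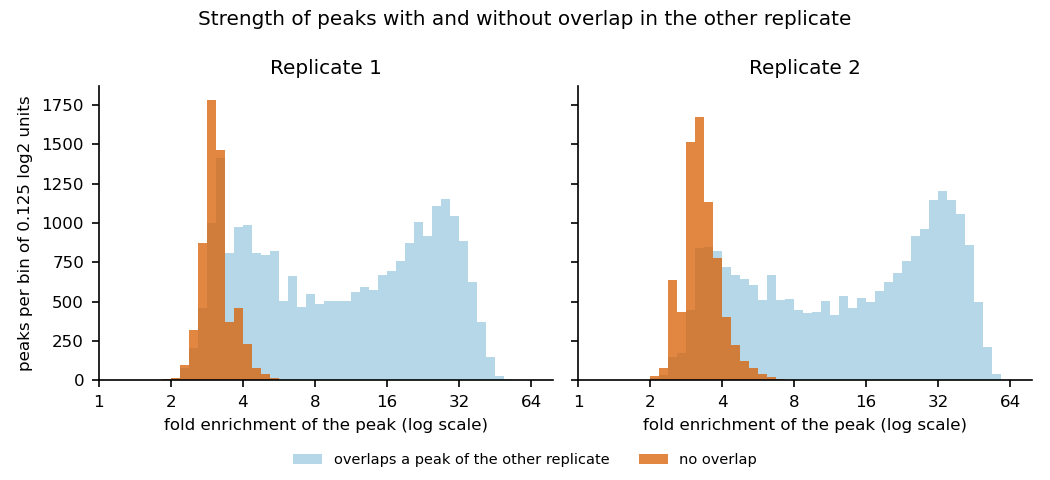
Number of peaks (vertical axis, per bin of 0.125 log2 units) by the authors' fold enrichment (horizontal log axis) in each replicate, for peaks that overlap a peak of the other replicate and for those that do not. The peaks without overlap sit at the low end, with median fold enrichments of 2.98 in replicate 1 and 3.27 in replicate 2.

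The second comparison asked where the mark lay. Of the 22403 replicated peaks, 15595 (69.6%, 95% Wilson interval 69.0 to 70.2) lay within 1 kb of a start site of a protein-coding gene, and these were also the strongest and widest, with a median fold enrichment of 25.4 and a median width of 1677 bp. A further 5.04% lay at start sites of other gene types, 9.72% in introns, 3.26% in exons and 12.3% between genes. The intronic peaks had a median fold enrichment of 4.35 and the intergenic ones 5.35. In each replicate's own list the share at protein-coding start sites was 59.0% and 58.5%. The replicated peaks of highest fold enrichment, which were picked after their values were seen, included those at Ythdf1, which encodes a reader of methylated RNA (chromosome 2, 180919576 to 180921402, fold 67.4), at the ubiquitin gene Ubc (chromosome 5, 125388153 to 125390429, fold 64.2) and at Fbxo11 (chromosome 17, 88062996 to 88067191, fold 64.4).

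In all, 14552 of 21938 protein-coding genes (66.3%) had a replicated peak within 1 kb of a start site and are called marked from here on. Chromosome 12 had the highest share (80.9%) and the Y chromosome the lowest, at 4 of 183 genes (2.19%). The 4 were Ddx3y, Eif2s3y, Kdm5d and Uty, which were named after they were seen. No Y peak of any list ended beyond position 1286914, while Y genes ran to 90839177. Whether reads could be placed on the rest of the Y is not known here, so the low share does not show absence of the mark. On the X chromosome 51.3% of genes were marked, against 67.6% on the autosomes. The share followed the CpG content of the promoter, from 0.957% in the lowest decile of observed over expected CpG to 99.5% in the highest.

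The third comparison asked which cell types' genes were marked. Every measured gene of the lists for nephron progenitors (15 of 15), early nephrons (15 of 15), podocytes (16 of 16) and endothelium (16 of 16) was marked. These include Six2, Wt1, Sall1, Eya1 and Gdnf of the progenitors, Lhx1, Pax8, Hnf1b and Jag1 of the early nephron, Nphs1, Nphs2 and Podxl of the podocyte filter, and Kdr, Flt1 and Pecam1 of blood vessels. The tubule lists were not complete, and no test compared them with the complete lists. In the proximal tubule list 13 of 18 genes were marked, among them Lrp2, Cubn and Hnf4a, while Kap, Miox, Slc22a8, Slc5a12 and Slc5a2 had no replicated peak. In the lists for the loop of Henle and the distal tubule, the unmarked genes included Umod, which encodes uromodulin, and Slc12a3, which encodes the thiazide-sensitive salt transporter.

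Against all other protein-coding genes, the 4 complete kidney lists were marked more often. Fisher's exact test (two-sided, Benjamini-Hochberg over 25 lists) gave p = 0.00409 and adjusted p = 0.00568 for each of the nephron progenitor and early nephron lists. The same exact test gave p = 0.00227 and adjusted p = 0.00379 for podocytes and for endothelium. The renal stroma list, with 16 of 18 genes marked and Lum and Ren1 unmarked, did not pass (exact test, p = 0.0462, adjusted p = 0.0577). Neither did the ureteric and collecting duct list, with 19 of 22 marked and Avpr2, Elf5 and Foxi1 unmarked (exact test, p = 0.0679, adjusted p = 0.0808). In the authors' pooled list both passed (adjusted p = 0.0146 and 0.0257 in the exact test). The proximal tubule (72.2% marked, adjusted p = 0.804 in the exact test), the loop of Henle (10 of 12, unmarked Cldn16 and Umod, adjusted p = 0.390 in the exact test) and the distal tubule (9 of 12, unmarked S100g, Slc12a3 and Trpv5, adjusted p = 0.793 in the exact test) did not differ detectably from other genes. Taken as 1 set, 129 of the 144 kidney list genes (89.6%) were marked, against 66.2% of other genes (exact test, p = 1.22e-10). The marked proximal tubule genes had weak peaks: 7 of 13 fell in the weakest 25% of the replicated list, and their median fold enrichment was 5.67, against 29.3 over all marked genes.

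Genes of other organs and of blood were mostly unmarked. In the hepatocyte list only Apoh of 16 genes was marked, and Alb, Afp, Apoa1 and Ahsg were not. Whether the peak at a marked gene belongs to a neighbouring gene was not tested. The germ line list had only Dazl marked among 16, and the list of macrophage and lymphocyte genes only Cd14 among 15, with Adgre1, Aif1, C1qa and C1qb unmarked. The erythroid list had 4 of 14 marked (Epor, Tfrc, Klf1 and Gypa), while Alas2, Epb42, Gata1 and the globin gene Hba-a1 were not. Skeletal and heart muscle (Ryr2, Actn2, Ckm and Tnni3 marked of 16 genes), adrenal gland (Nr5a1, Phox2a, Chgb and Chga of 16), the epithelia of lung and intestine (Lgr5, Nkx2-1, Cdx2 and Cdx1 of 16) and pancreas (Nkx6-1, Ptf1a, Pdx1 and Neurog3 of 15) each had 4 genes marked. Of these 4 lists, unmarked genes included Acta1, Cyp11a1, Muc2 and Gcg. All 8 lists passed the exact test as marked less often than other genes, with adjusted p from 4.39e-06 (hepatocyte and germ line) to 0.00995 (erythroid). The muscle list lost this call with a 2500 bp window, in the pooled list and without replicate 1 (adjusted p from 0.0678 to 0.0793 in the exact test). The genes of smell and pheromone receptors were nearly bare: 3 of 1093 olfactory receptor genes (Olfr94, Olfr56 and Olfr1033) and 1 of 327 vomeronasal receptor genes (Vmn1r4) were marked, the latter with an adjusted p of 1.6e-153 in the exact test. The neuron list had 14 of 16 genes marked, with only Camk2a and Tubb3 unmarked (adjusted p = 0.124 in the exact test, and 0.0349 in the pooled list, where it passed as marked more often). Its share, 87.5%, was near the 84.7% of random lists matched on promoter CpG content (log2 odds ratio 0.28, adjusted p = 1 by matched permutation). Its marked genes, such as Gad1 and Rbfox3, lay at a median percentile of peak strength of 50.2 in replicate 1 and 50.1 in replicate 2, against 78.4 in both for all marked genes.

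Genes used by most cells were nearly all marked, and so were the clustered Hox genes, which are a separate class. All 19 cell cycle genes, all 16 genes of the primary cilium and cystic kidney disease and all 14 glycolysis gene records passed the exact test, with adjusted p of 0.00199, 0.00379 and 0.00568. With the 5' end of the gene as its only start site, the glycolysis log2 odds ratio fell from 3.88 to 1.57 and the call ended (adjusted p = 0.116 in the exact test). The ribosomal protein genes (79 of 82, adjusted p = 2.97e-10 in the exact test) lacked a peak only at Rpl10l, Rpl39l and Rpl3l, and the Hox genes (38 of 39, adjusted p = 1.27e-05 in the exact test) only at Hoxc12.

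Promoter CpG content bore on these calls. Against random lists matched on its decile, 14 of the 19 lists that had passed no longer did. Among them were nephron progenitors, early nephrons and podocytes, whose matched random lists were themselves marked at 92.0%, 93.1% and 94.2% and so left little room for a difference. The cell cycle, cilium, glycolysis, ribosomal protein and Hox lists, whose matched lists were marked at 92.7% or more, also lost their calls. Of the 8 lists of blood and other organs marked less often, 6 lost theirs, with adjusted p by matched permutation from 0.0643 for hepatocytes to 1 for erythroid genes, whose share (28.6%) lay above that of their matched lists (25.2%). The pancreas (adjusted p = 0.049) and germ line (adjusted p = 0.000167) lists still passed this permutation test as marked less often, as did both receptor families. Endothelium was still marked more often (100% against 56.9%, matched permutation, adjusted p = 0.000167). Proximal tubule (72.2% against 43.8%, adjusted p = 0.0147 by matched permutation), loop of Henle (83.3% against 57.1%, adjusted p = 0.0429 by matched permutation) and renal stroma (88.9% against 64.9%, adjusted p = 0.0147 by matched permutation) passed when matched in this way. None of these lists passed the main unmatched test on the replicated list. Renal stroma did pass unmatched with the 5' end of the gene only (adjusted p = 0.0321 in the exact test). The matched test was run on the main setting only, where 7 of the 13 marked proximal tubule genes had peaks in the weakest 25%. Whether that list would pass matched without weak peaks was not tested. These tests run over genes, which are not independent replicates, and describe these 2 pools of kidneys.

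**Figure D2:**
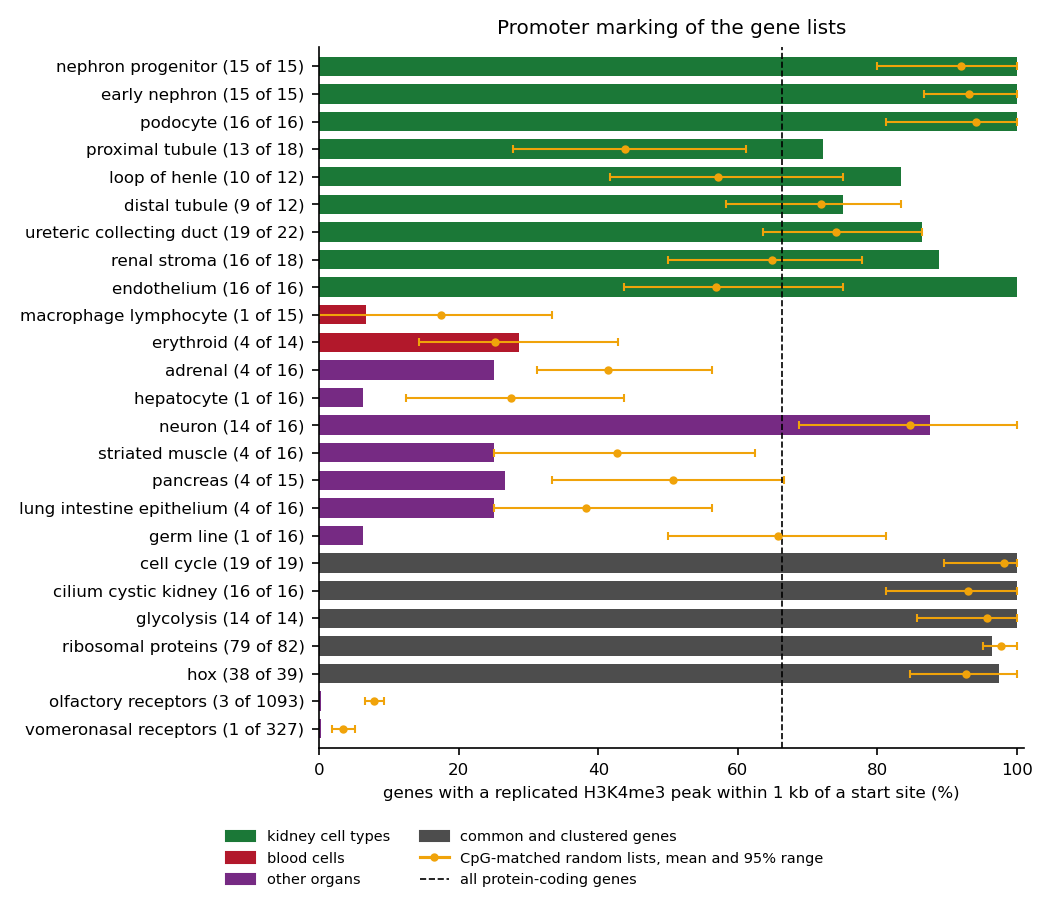
Percent of each list's genes with a replicated H3K4me3 peak within 1 kb of a start site (bars, from 0), with the mean and the 95% range of random lists matched on promoter CpG content (points and whiskers) and the share of all protein-coding genes, 66.3% (dashed line). The kidney lists run from 72.2% to 100%, and 1 other-organ list, that of neurons, reaches 87.5%.

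The fourth comparison asked how far the mark extended over each promoter. The 10 widest domains, ranked by mean log2 width and counting genes that share a domain once, all lay at developmental transcription factor genes. The first 3 were the Hoxb3 to Hoxb8 stretch on chromosome 11 (52254 ± 73.5 bp, SD, n = 2 replicates, as for all widths below), the Hoxa stretch on chromosome 6 (33693 ± 11378 bp at Hoxa10) and the Hoxd8 to Hoxd11 stretch on chromosome 2 (30867 ± 40.3 bp). Next came Nr2f2, a nuclear receptor gene (chromosome 7, 70351944 to 70366735, 25232 ± 275 bp), Gata3, a gene of the ureteric duct (chromosome 2, 9857078 to 9890034, 21591 ± 231 bp), and Meis2 (chromosome 2, 115863064 to 116065839, 20971 ± 691 bp). The Hoxc stretch on chromosome 15 (19723 ± 7906 bp at Hoxc9), Tbx2 (14115 ± 2266 bp), Sim1 (13058 ± 84.1 bp) and Wt1 (12055 ± 803 bp) completed the 10. The median domain at a marked gene was 1821 bp in replicate 1 and 1950 bp in replicate 2.

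**Figure D3:**
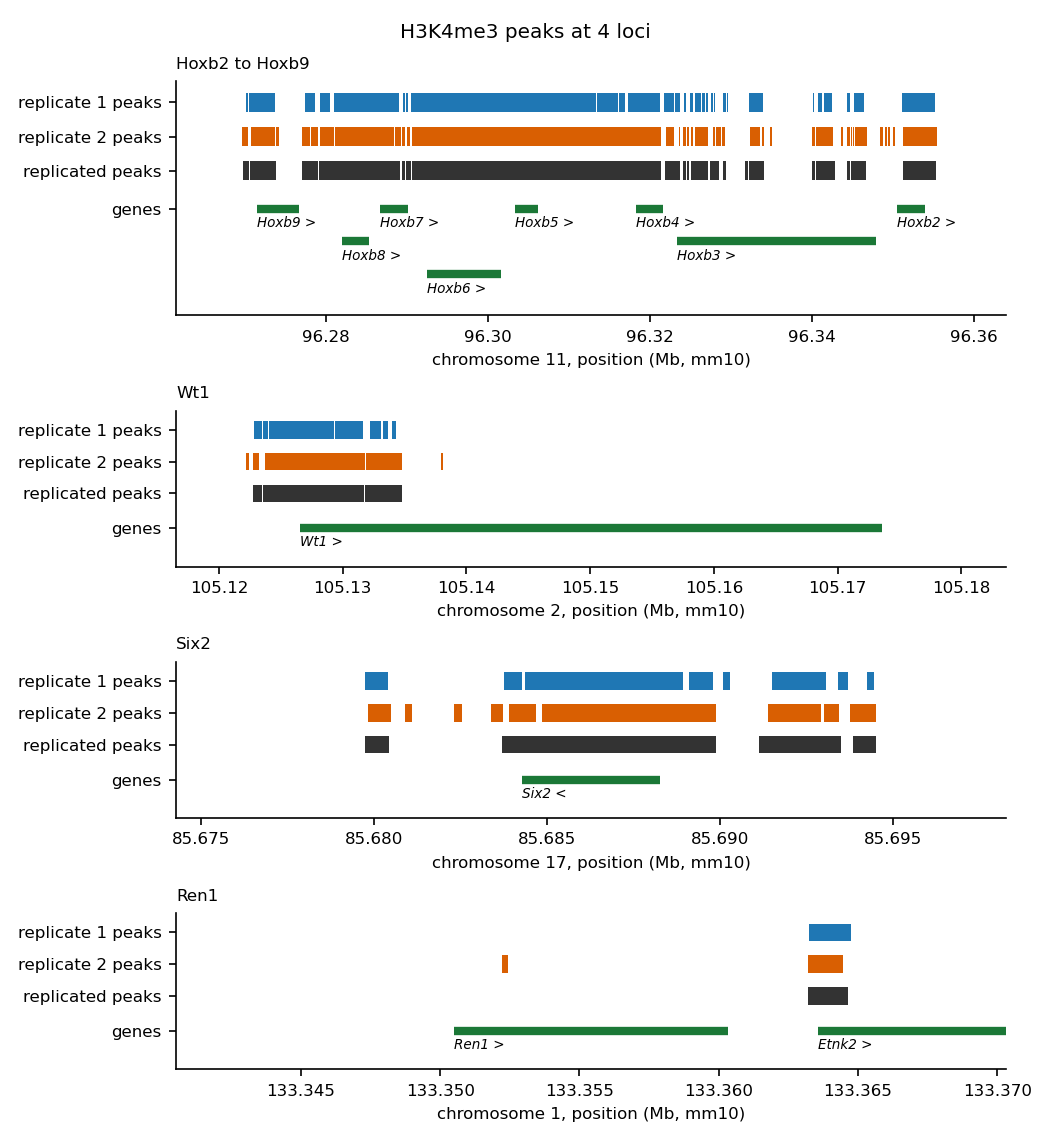
Peaks of each replicate and replicated peaks (boxes) and protein-coding genes (lower bars, with the direction of transcription) along chromosome position in Mb on mm10, at Hoxb2 to Hoxb9, Wt1, Six2 and Ren1. Peaks cover much of the Hoxb stretch and the starts of Wt1 and Six2 in both replicates, while Ren1 has a single 200 bp peak in replicate 2 and the neighbouring peaks lie at Etnk2.

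Domains were wide at genes of the developing kidney. At nephron progenitor genes the geometric mean width was 4643 bp in replicate 1 and 5897 bp in replicate 2, and over both it was 2.84 times that of other marked genes. Besides Wt1, the widest were at Hoxd11 (30867 ± 40.3 bp) and Hoxa11 (24239 ± 24747 bp), and that at Six2 spanned 7060 ± 728 bp. The early nephron genes (4558 and 5150 bp) were led by Pou3f3 (11222 ± 2491 bp), Lhx1 (9685 ± 1117 bp) and Hnf1b (8831 ± 41.0 bp). The stromal genes (4269 and 4410 bp) were led by Meis2, Meis1 (11502 ± 3824 bp) and Pbx1 (9627 ± 75.7 bp), the ureteric and collecting duct genes (2633 and 3428 bp) by Hoxb7, Gata3 and Emx2 (12138 ± 2505 bp), and the podocyte genes (2796 and 3083 bp) by Tcf21 (8692 ± 653 bp), Foxc2 (8641 ± 348 bp) and Mafb (6659 ± 552 bp). At endothelial genes (2554 and 3124 bp) the widest domains were those of Ets1 (5337 ± 812 bp), Esam (4709 ± 361 bp) and Flt1 (4375 ± 1425 bp).

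The difference in mean log2 width from other marked genes was tested by permutation of genes (100000 resamples, two-sided, Benjamini-Hochberg over 14 lists). It was 1.50 for nephron progenitors, 1.39 for early nephrons, 1.23 for stroma and 2.26 for Hox genes, each with a permutation p of 1e-05, the smallest that these resamples can give, and an adjusted p of 3.5e-05. It was 0.70 for the ureteric and collecting duct list (permutation p = 0.00022, adjusted p = 0.000513), 0.67 for podocytes (permutation p = 0.00127, adjusted p = 0.00254) and 0.61 for endothelium (permutation p = 0.00258, adjusted p = 0.00401). With peaks left unmerged, the ureteric and endothelial lists no longer passed (adjusted p = 0.204 and 0.600 by permutation). The Hox genes share domains and include 3 members of other lists. These are Hoxd11 and Hoxa11 of the nephron progenitors and Hoxb7 of the ureteric and collecting duct list. Neither of those lists was tested without its Hox members, which were among its widest. With each domain counted once, which was chosen after the data were seen, the difference of the Hox list came to 1.12 over 22 domains (adjusted p = 3.5e-05 by permutation).

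Loop of Henle and neuron list genes went the other way. Domains of the loop of Henle genes averaged 1050 bp in replicate 1 and 1036 bp in replicate 2 and were narrower than those of other genes by a log2 difference of -0.83 (permutation p = 0.00169, adjusted p = 0.00296). The widest were at Cldn10 (2571 ± 358 bp), Ptger3 (2224 ± 833 bp) and Esrrb (2039 ± 151 bp). Neuron list domains, led by Gad1 (2882 ± 337 bp) and Rbfox3 (2302 ± 326 bp), were also narrower (log2 difference -0.61, permutation p = 0.0046, adjusted p = 0.00644). The Gad1 value averages 2 domains that did not overlap, at 70566006 to 70569125 in replicate 1 and 70561879 to 70564522 in replicate 2. Within deciles of peak strength, neither list passed: the loop of Henle difference shrank to -0.17 (adjusted p = 0.555 by permutation), and that of the neuron list turned to 0.36 (adjusted p = 0.187 by permutation). The loop of Henle list did not pass within CpG deciles either (0.142 by permutation), nor did the neuron list with merging over 3 kb (0.345 by permutation). Proximal tubule domains, led by Lrp2 (5268 ± 519 bp) and Hnf1a (3466 ± 450 bp), did not pass (log2 difference -0.24, adjusted p = 0.304 by permutation). The difference was -0.081 without replicate 1 and -0.47 without replicate 2, with geometric mean widths of 1286 bp in replicate 1 and 1897 bp in replicate 2. With peaks left unmerged they passed as narrower (log2 difference -0.64, adjusted p = 0.00782 by permutation). Glycolysis genes such as Gapdh (3614 ± 19.8 bp) were wider by 0.48 (permutation p = 0.0249, adjusted p = 0.0317) and ribosomal protein genes such as Rpl18 (5416 ± 363 bp) by 0.35 (permutation p = 0.0001, adjusted p = 0.00028), and neither passed within deciles of peak strength (adjusted p = 0.0946 and 0.222 by permutation), nor ribosomal protein genes within CpG deciles (0.0994 by permutation). Cell cycle genes, led by Mki67 (4120 ± 4.9 bp), and cilium genes, led by Glis2 (5270 ± 1130 bp), did not pass (adjusted p = 0.0601 and 0.616 by permutation). Cell cycle genes passed as wider with peaks left unmerged, without replicate 1 and with each domain counted once (adjusted p from 0.0342 to 0.0447 by permutation). Fewer than 10 members of the distal tubule list had a width to test, and its widest domain was that of Cnnm2 (5108 ± 1044 bp).

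**Figure D4:**
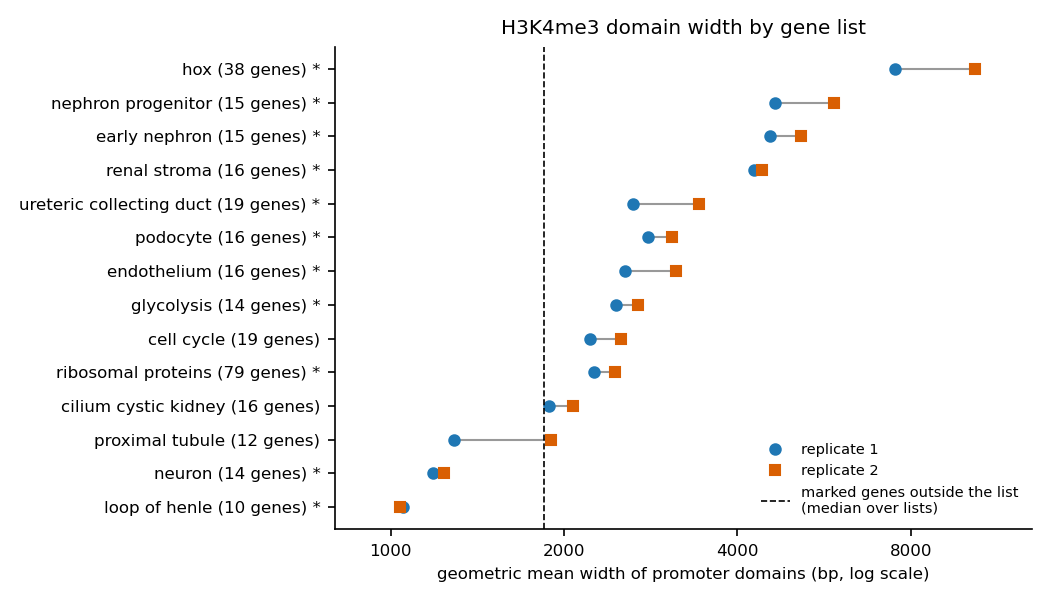
Geometric mean width in bp (log axis) of the promoter domains of each list's marked genes in replicate 1 (circles) and replicate 2 (squares), with the median over lists of the width at marked genes outside the list (dashed line). Asterisks stand for an adjusted p under 0.05 by permutation. Hox genes lie highest in both replicates, at 7522 and 10365 bp, and loop of Henle genes lowest, at 1050 and 1036 bp.

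The last comparison asked whether the same genes had broad domains in both replicates. Early nephron genes stood out most among the kidney lists, with 10 of 15 in the widest 5% of both replicates, followed by nephron progenitor (7 of 15), stromal (7 of 16), podocyte (6 of 16) and ureteric and collecting duct genes (4 of 19). Fisher's exact test against other marked genes, of which 3.8% to 3.9% were broad, gave adjusted p from 1.26e-10 for early nephrons to 0.0127 for the ureteric list. This test was not among those fixed beforehand, and it uses the same widths as the permutation test. Only 2 of 16 endothelial genes were broad in both (adjusted p = 0.252 in the exact test), and none of the 10 loop of Henle genes and none of the 14 neuron genes were. Of the 724 genes in the widest 5% of replicate 1, 561 (77.5%, 95% Wilson interval 74.3 to 80.4) were also in the widest 5% of replicate 2, where independent lists would share 36.2. Over the 14460 genes with a domain in both replicates, Spearman's rho of the widths was 0.906, across genes that are not independent, and 92.2% of genes differed by less than 1.5-fold. The domain was wider in replicate 2 for 66.4% of genes, with a median ratio of 1.05.

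The largest ratios of width between the replicates were at Pygm, the muscle glycogen phosphorylase gene (331 bp in replicate 1 and 4806 bp in replicate 2), Ccr10 (736 and 9017 bp), Wnt1 (400 and 4539 bp), Hcar1 (296 and 3096 bp) and Mvp (898 and 8686 bp). At Pygm the 2 domains lay at different places, 6392644 to 6392974 and 6398425 to 6403230 on chromosome 19. The replicate 2 domain lay mostly past the 3' end of the gene at 6398459. At Hoxa11 the width was 6740 bp in replicate 1, where gaps of over 1 kb split the Hoxa stretch, and 41738 bp in replicate 2, where no gap between the merged peaks was over 1 kb.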

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

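Of the 22403 replicated peaks, 11 lie on scaffolds with no position within an assembled chromosome. The gene comparisons do not cover these scaffolds, and the peaks were picked out for that reason. The strongest of them spans 2191 bp with a fold enrichment of 28.1 and a −log10 q of 139.7, and their median fold enrichment is 6.80, against 25.4 at protein-coding promoters. No explanation for them was tested, and with 2 samples in the group no replicate could be tested as standing apart.

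The peaks found in 1 replicate only were a second pattern to weigh, with a test written before its result was seen. If they were weak peaks near the caller's threshold, their median percentile of strength within their own list should lie under 30 in both replicates. It was 14.2 in replicate 1 and 17.796 in replicate 2, consistent with peaks near the threshold. A difference in depth between the libraries stays open, as the number of reads is not known, and no biological explanation was tested, since the design holds 1 group.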

How the results depend on the processing

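The overlap rule and the q threshold both moved the replicate overlap. With a reciprocal overlap of 50% it fell to 65.0% and 65.1% of the peaks of replicates 1 and 2, while with a −log10 q of at least 2 it was 88.4% and 80.7%, and of at least 5, 97.2% and 88.6%. The rank correlation of fold enrichment was 0.963 with the reciprocal overlap and 0.839 with a −log10 q of at least 2. The share of peaks at promoters was 67.4% with a 500 bp window, 74.9% with 2500 bp, 58.7% in the pooled list, and 58.5% to 59.0% with either replicate left out. The number of marked genes stayed between 13761 and 14771 under all its alternatives. Broad domains shared by the replicates came to 73.8% with merging over 3 kb.

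Of 248 recomputed list markings, 213 kept their direction and side of the threshold. Matching on promoter CpG content left 4 lists marked more often and 4 less often, where 9 and 10 had been, and turned the log2 odds ratio of the erythroid list to 0.22 and of ribosomal proteins to -0.59, neither past the threshold. The proximal tubule list, never past the threshold unless matched on CpG content, turned to -0.93 with a −log10 q of at least 5, to -0.45 with the 5' end of the gene only and ran from -0.048 without replicate 2 to 0.66 without replicate 1, and the distal tubule list to -0.30 with the 5' end only. The loop of Henle log2 odds ratio rose from 1.09 to 1.95 without replicate 2 and stayed short of the threshold. Calls gained were renal stroma (pooled list, 5' end only, either replicate left out), ureteric and collecting duct (pooled list, 5' end only, without replicate 1) and neurons, marked more often (pooled list, either replicate left out). Calls lost outside the CpG matching were glycolysis (5' end only) and striated muscle (2500 bp window, pooled list, without replicate 1). Of 125 recomputed widths, 108 kept direction and side. Where 2 lists had been narrower, 1 was with merging over 3 kb, 1 with a −log10 q of at least 2 (where the loop of Henle list was too short to test), 1 within CpG deciles and 0 within deciles of peak strength, but 3 with peaks unmerged, when the proximal tubule list passed at -0.64. The proximal tubule log2 difference turned to 0.026 with a −log10 q of at least 2, 0.27 within CpG deciles and 0.45 within deciles of peak strength, where neurons turned to 0.36 and the cilium list to -0.042, none past the threshold. The wider nephron progenitor, early nephron, podocyte, stromal and Hox lists passed under each alternative run. Apart from the matched comparisons, the cause was not tested. These matched by decile, which reduces differences in CpG content or strength but leaves those within a decile. The background without receptor genes, single counting of domains and the deciles of peak strength were chosen after seeing the data. The unknown depth limits what the weak peaks can show: a gene without a peak is one where the authors' caller listed none.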

Other observations

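The other gene types counted carried the mark less often than the 66.3% of protein-coding genes, to very different degrees, and no test compared the types. Of 790 processed transcript genes 52.3% had a replicated peak within 1 kb of a start site, of 2959 antisense genes 34.9%, of 5854 lincRNA genes 14.1%, and of 9940 processed pseudogenes 1.55%. Genes whose 5' end lay over 2500 bp from any protein-coding start site were also counted apart. Their shares were 26.4% of 413 processed transcript genes, 8.31% of 5334 lincRNA genes and 8.59% of 1630 antisense genes. A peak at any start site of such a gene counted, so some of these peaks may lie at protein-coding promoters. Strong peaks also lay over 1 kb from any annotated start site. The strongest was inside an intron, 3933 bp from the start of the pseudogene Gm13039 and 32065 bp from the nearest start of a protein-coding gene, Prdm2 (chromosome 4, 143160755 to 143162670, fold enrichment 48.1). The next lay 16061 bp from the noncoding gene Lncppara and 60340 bp from Ppara, a gene of fatty acid use (chromosome 15, 85669677 to 85674643, 4967 bp wide, fold enrichment 42.9). It was followed by a peak in an exon 2540 bp from the start of Sf3b5 (chromosome 10, 13007883 to 13009756, fold enrichment 41.9) and an intergenic one 32436 bp from Pum2 (chromosome 12, 8640403 to 8641698, fold enrichment 41.7).

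Transcription factor genes outside the Hox clusters (16 families such as Sox, Fox, Pax, Irx and T-box, chosen with their test after list widths had been seen) were marked at 156 of 176 genes. The widest domains among members that no kidney list holds were at Tbx2 (14115 ± 2266 bp, SD, n = 2), Pax2, a regulator of kidney formation (12854 ± 6780 bp), Osr2 (10087 ± 76.4 bp), Gata6 (9779 ± 1767 bp) and Gata2 (9117 ± 1519 bp). One hypothesis is that the kidney lists have wide domains only because they hold members of such families. Kidney list members should then be no wider than other marked members. The 22 kidney list members had a geometric mean width of 6666 bp and the 133 others 2269 bp, a log2 difference of 1.55 (two-sided permutation p = 1e-05, the smallest these resamples can give). Membership of these 16 families alone does not account for that difference. The families and the test were chosen with the list widths known, so the permutation p is not independent support. Outside the families and Hox, 103 kidney list genes differed from 14164 others by 0.35 (permutation p = 1e-05). The mean difference was thus larger within the families. Wide domains were not confined to them: 17 of the 22 kidney list members and 18 of the 103 outside were broad in both replicates. Among the comparison genes, 13.5% were broad inside the families and 3.42% outside. The lists name genes already known from kidney, and some of the 133 others, such as Pax2, are kidney genes too. The 16 families leave out other transcription factor genes with wide domains, such as Nr2f2 and Sim1. Transcription factor status in general was thus not weighed as an explanation.

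The CpG content of promoters, with a test written beforehand, was weighed as the reason that kidney lists were marked more often. Matched random lists were marked at 71.6% (95% range 66.7 to 76.4), and the 144 kidney list genes at 89.6% (permutation p = 2e-05, the smallest these resamples can give two-sided). CpG content, as matched by decile, thus does not account for the whole difference, and differences within a decile were not matched. It could account for part of it, since the matched lists lay above the 66.2% of all other genes. Matched one by one, the lists moved both ways. Of the complete lists, 3 with little room left for a difference no longer passed, the nephron progenitor list with a log2 odds ratio of 1.89. The proximal tubule, loop of Henle and renal stroma lists then passed, with matching run on the main setting only. The 111 genes of the other organ lists together were marked at 28.8%, against 50.3% in their matched lists (permutation p = 2e-05).

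The adrenal glands lie on the kidneys, and tissue left on them was weighed as a source of marked adrenal genes, again with a test written beforehand. Of 8 genes of steroid-making cells in the list only 1 was marked, where matched random lists gave 1.82 (permutation p = 0.681). The marked gene, Nr5a1, encodes a transcription factor, while Star and the enzyme genes Cyp11a1, Cyp17a1, Hsd3b1, Cyp21a1 and Cyp11b1 were unmarked, as was the receptor gene Mc2r. Marking above the matched lists, which leftover adrenal tissue predicted, was thus not seen. Marker genes of kidney cells, such as Umod and Ren1, were unmarked too. The test therefore sets no limit on how much adrenal cortex the sample held. Outside the 8 genes fixed beforehand, the list also holds the steroid enzyme gene Cyp11b2, which was unmarked. Among the remaining adrenal list genes, Phox2a, Chga and Chgb were marked, while Th, Dbh, Phox2b and Pnmt, which also belong to catecholamine-making cells or their development, were not. No explanation for this split was tested.

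At 4 places peaks had a fold enrichment under 2.5 with a −log10 q of at least 20, a pairing seen at no other replicated peak: on chromosome 17 from 39843076 to 39846768 and from 39848003 to 39848888, the latter at a gene annotated as ribosomal RNA, on chromosome 11 at Sfi1 (3192188 to 3194303) and on chromosome 2 at Gm10800 (98666490 to 98667431). Of these, Sfi1 and Gm10800 count as marked protein-coding genes.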
